A study of Dictyostelium discoideum with 9 samples.

How the data were processed

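RNA was measured by bulk sequencing in Ax2 amoebae of Dictyostelium discoideum kept for 3 days on E. coli B/r, S. salivarius 24SMBc or S. mutans, with 3 libraries per group and 9 in all. Per the labels' protocols, cells were first grown in axenic medium, then shaken in Soerensen buffer with the bacteria, and libraries were made from total RNA with an Illumina TruSeq RNA kit. The deposited table holds raw counts, whole numbers per gene and library, and per the submitters' processing notes Trimmomatic 0.38, HISAT2 2.2.1, StringTie 2.1.3b and DESeq2 1.52 were used, with no role or order given; the genome build, the annotation and the strand setting are not given in the sources used here. The table had 13659 rows, of which 7 carried no gene name and held 0 counts; the other 13652 were matched by locus tag to the supplied RefSeq gene names, and 4126 had a symbol. Columns were matched to samples by the library names in the labels.

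Libraries held 38935843 to 48677714 counts. A floor of 3 counts over a group corresponded to 0.0271 library-scaled counts (CPM, each library set to the same scaled total) on E. coli, 0.0212 on S. salivarius and 0.0200 on S. mutans. CPM values were scaled with TMM (trimmed mean of M values) factors, which were 0.780 to 0.903 on E. coli, 0.933 to 1.1 on S. salivarius and 0.929 to 1.43 on S. mutans. No replicate pair was a repeat of 1 library: the chi-square per degree of freedom between replicates was 51.4 or more.

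Genes were kept with filterByExpr by group (9938 tested) and fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest, 2-sided) on all 9 libraries with group means alone, leaving 6 residual degrees of freedom. Benjamini-Hochberg adjustment ran over all tested genes within each of 3 comparisons (S. salivarius against E. coli, S. mutans against E. coli, and S. salivarius against S. mutans), with calls at an adjusted p under 0.05. Gene lists were tested with camera in limma 3.58.1 (2-sided, preset correlation 0.01, lists with at least 5 tested members, adjusted over lists within a comparison), beside camera with a correlation estimated from the data and fry. Counts adjusted over a list alone used Benjamini-Hochberg adjustment within that list, with no adjustment over the lists. They are given for lists that passed in camera on the same data, so they are no independent support. All computing used R 4.3.3, and figures Python 3.11.15 with matplotlib 3.10.9.

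The comparisons, the tests, 42 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Of the lists, 38 were tested, 1 (amoebapore-like genes) had fewer than 5 tested members, and 3 (glutathione transferases, cytochrome P450 and transposable elements) matched no symbol as written. The list of cytosolic ribosomal proteins held 79 genes as fixed, 2 of them encoded in the mitochondrion, and lists without members whose identity goes against the list's name were run as an alternative. Genes were named by rule: per comparison, up to 8 with the largest rise and 8 with the largest fall among called genes with a symbol, a mean of at least 10 CPM in the higher group, no overlap between the groups' libraries and at most 2 genes sharing the first 3 letters; the 2 members with the smallest p in the direction of each called list; and 12 core genes in every comparison. The text names a subset, leaving out genes mostly, though not only, from the end of each ranking, and ecmA, a core gene, had too few counts to test. Genes named outside this rule are marked as chosen after their values were seen. Fold changes against a group at 0 counts are bounds against the floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with its counting interval.

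Replicate numbers occur in every group. The deviations of same-numbered S. salivarius and S. mutans libraries from their group means correlated at 0.283, 0.431 and 0.112, so these numbers were read as pairing those groups, with no statement in the labels. With 3 libraries per group such a match can arise by chance, and no chance level was computed. Pairs with E. coli libraries gave -0.0602 to 0.0184 and were not read as pairs. A fit with the replicate number as a block was run as an alternative.

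The tests were tested on simulated data with 200 changed genes, 100 at each log2 size. For sizes of 1 and 2, edgeR called 5% and 54% (S. salivarius against E. coli, 4 false calls), 4% and 51% (S. mutans against E. coli, 6 false) and 1% and 46% (between the streptococci, 2 false). DESeq2 1.42.0 called 19% and 76% (32 false), 29% and 85% (48 false) and 11% and 81% (30 false).

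The overlap of both responses was set against 20 simulations of unchanged groups that share the same E. coli libraries. Alternatives were DESeq2 and limma-voom, RLE and upper-quartile scaling, no filter or at least 50 counts in 3 libraries, only the 6 libraries compared, the replicate block, a minimum absolute log2 fold change of 1, leaving out mitochondrial and ribosomal RNA genes, and leaving out each library in turn. Scaling to library size alone, leaving out E. coli replicate 1 and S. mutans replicate 1 together, library quality weights, corrected lists and the block on only the 6 libraries compared were chosen after seeing the data. No library was left out of the main results.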

Results

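Transcripts were counted in Ax2 amoebae of Dictyostelium discoideum kept for 3 days in shaken buffer with 1 kind of bacterium as their only food: Escherichia coli B/r, the standard laboratory food, Streptococcus salivarius 24SMBc, a probiotic, or Streptococcus mutans, an oral pathogen. Each group had 3 libraries, of 42932763 to 46441459 counted reads on E. coli, 45719060 to 48677714 on S. salivarius and 38935843 to 43668441 on S. mutans, and 9938 genes had enough counts to test. The labels do not say whether replicates were separate cultures, so each p measures the spread between these samples. All 9 libraries share 1 estimate of that spread, so each p also rests on the group outside its comparison.

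The libraries on E. coli lay apart from those on the streptococci. Across genes, which are not independent replicates, log2 values of E. coli libraries correlated with those of S. salivarius libraries at r = 0.818 to 0.916 and with those of S. mutans libraries at r = 0.782 to 0.896, while pairs within a group gave 0.936 to 0.984 (E. coli), 0.957 to 0.978 (S. salivarius) and 0.916 to 0.973 (S. mutans). Pairs of S. salivarius and S. mutans libraries gave 0.896 to 0.968, which overlaps the range within S. mutans through S. mutans replicate 1 alone: S. mutans replicates 2 and 3 correlated at 0.973, and at 0.896 to 0.9503 with the S. salivarius libraries. S. mutans replicate 1 lay nearer the S. salivarius libraries (mean r = 0.964) than the other two S. mutans libraries (0.918), and E. coli replicate 1 stood apart from the other two E. coli libraries (0.938). Genes of cytosolic ribosomal proteins, the protein part of the translation machinery, took 33.0 ± 1.86% of counts on E. coli, 23.2 ± 4.63% on S. salivarius and 13.4 ± 8.89% on S. mutans (mean ± SD, n = 3), with 23.5%, 6.60% and 10.2% in S. mutans replicates 1, 2 and 3. Discoidins, lectins made in quantity around the onset of starvation, took 0.301 ± 0.0820%, 4.22 ± 1.21% and 2.21 ± 0.440% of counts.

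**Figure D1:**
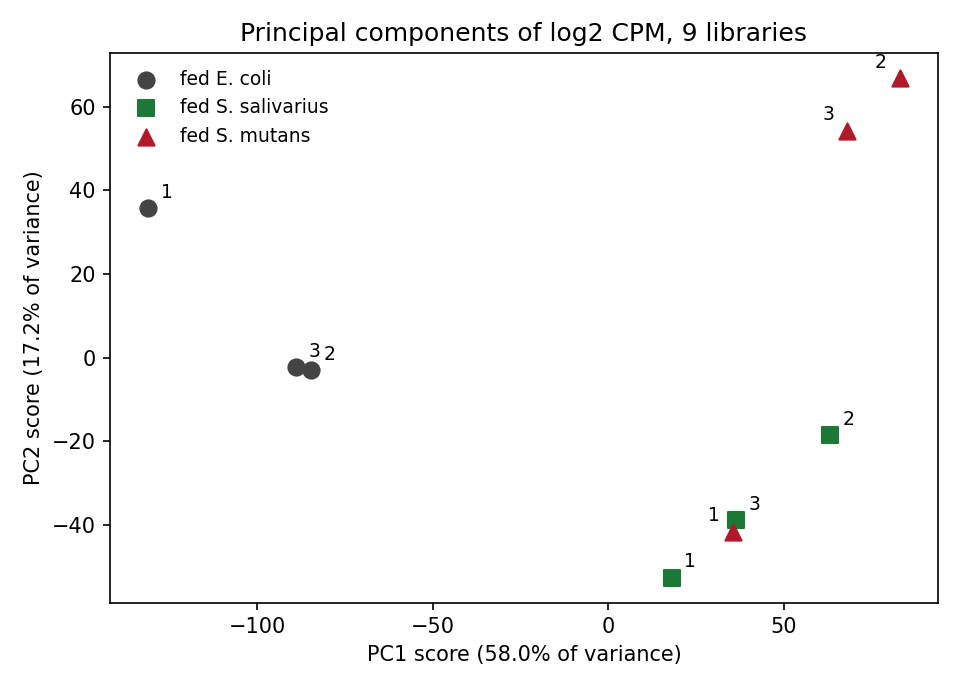
Each point is 1 of the 9 libraries, placed by its first (horizontal, 58.0% of variance) and second (vertical, 17.2%) principal component score of log2 library-scaled counts (CPM), with its replicate number beside it. E. coli libraries lie to the left of all 6 libraries on streptococci, and S. mutans replicate 1 lies among the S. salivarius libraries.

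On S. salivarius, 18 of 27 early development genes were higher than on E. coli, and 8 of 11 lysosomal protease genes were lower and 1 higher. As sets both lists passed in camera, a test of gene lists, with its preset correlation between genes but not with a correlation estimated from the data (adjusted p = 0.28 and 0.133). csaA, which encodes the aggregation-stage adhesion protein contact site A, averaged 1327 ± 590.3 CPM on S. salivarius and 152 ± 47.0 on E. coli (mean ± SD, n = 3; log2 fold change ± standard error 3.12 ± 0.44, adjusted p = 0.00124, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, used for each gene below unless another tool is named). cprF, a cysteine protease gene, averaged 20.01 ± 7.30 CPM against 1234.3 ± 105 (-5.95 ± 0.70, adjusted p = 0.000504). In all, 1341 genes were higher and 781 lower at an adjusted p under 0.05. The share of called genes that were higher, 63.2%, was 50.8% with upper-quartile scaling (median of all genes -0.15, against 0.04 with the main scaling) and 82.0% when scaled to library size alone (median 0.32). The count of 2122 genes became 1165 without E. coli replicate 3, 1101 without S. salivarius replicate 2 and 1160 without S. salivarius replicate 3. It became 3061 without S. mutans replicate 1, which enters only through the shared scaling, filter and spread, and 2954 when only the 6 libraries compared were fitted.

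Of 27 tested members of the early development and cAMP signalling list, 18 rose on S. salivarius, 0 fell and 9 did not pass, and 18 rose when adjusted over the list alone (median log2 fold change 2.28, camera adjusted p = 5.61e-12; adjusted p = 0.28 with an estimated correlation). Among them were acaA, the adenylyl cyclase of aggregation (3.23 ± 0.45, adjusted p = 0.00124), carA-1, the cAMP receptor cAR1 (2.28 ± 0.35, adjusted p = 0.00198), pkaR, the regulatory subunit of protein kinase A (2.99 ± 0.29, adjusted p = 0.000245), and dhkC, a histidine kinase (5.21 ± 0.39, adjusted p = 9.33e-05). cadA, which encodes a calcium-dependent cell adhesion protein, rose from 106 ± 59.0 to 3957 ± 1023 CPM (5.23 ± 0.62). All 7 discoidin genes rose, and all 7 when adjusted over the list alone (median log2 fold change 3.28, camera adjusted p = 5.61e-12; adjusted p = 0.28 with an estimated correlation); dscE rose from 97.8 ± 37.3 to 952 ± 81.0 CPM (3.28 ± 0.34, adjusted p = 0.000286) and dscA-1 from 915 ± 279 to 12105 ± 3390.3 CPM (3.73 ± 0.40). Values of dscA-1 and dscA-2, and of other pairs named -1 and -2, are uncertain as single genes, because in 58 of 60 such pairs the counts lay within 10% of each other. Both copies of a pair count as separate members in list counts and list tests. Counts that hold such pairs, those of the discoidins among them, may therefore overstate the number of independent genes in every comparison.

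In the Tgr family, membrane proteins that include the self-recognition pair TgrB1 and TgrC1, 6 of 11 tested members rose and 0 fell, with 8 up and 1 down when adjusted over the list alone (median log2 fold change 5.89, camera adjusted p = 0.000129; adjusted p = 0.622 with an estimated correlation). The median was 3.42 with the 4 members at very few counts in a group set to their bound. tgrB1 rose from 3.48 ± 0.463 to 221 ± 146 CPM (5.99 ± 0.62, adjusted p = 0.000286) and tgrR1 from 4.94 ± 1.58 to 86.6 ± 42.2 (4.13 ± 0.45, adjusted p = 0.000349). Without a filter on low counts the family did not pass (adjusted p = 0.0712).

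The genes with the largest rises included several near or at 0 counts on E. coli. For each, all 3 S. salivarius libraries lay above all 3 E. coli libraries (5% of genes by chance). The naming rule requires this, so it is no support for the rises. cbpC, a calcium-binding protein gene, had 0 counts on E. coli and 23.4 ± 9.79 CPM on S. salivarius, at least 863-fold higher against a floor of 3 counts over the group, and limA was at least 389-fold higher on the same floor. cbpF, a further calcium-binding protein gene with 3 counts on E. coli, had a ratio of 2288 (95% counting interval 783 to 11094). Floors and counting intervals cover counting error alone. phdA, a PH domain protein gene of chemotaxis, rose from 0.760 ± 0.408 to 327 ± 322 CPM (8.75 ± 1.04, adjusted p = 0.000511) and csbC from 2.19 ± 0.834 to 405 ± 149.7 (7.53 ± 0.58, adjusted p = 9.87e-05). Also among the largest rises were cmbC (10.83 ± 1.58), prtA (9.22 ± 1.09) and nagD, an N-acetylglucosaminidase gene (9.05 ± 1.49).

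Of 32 heat shock and chaperone genes, 17 rose and 4 fell on S. salivarius, 17 and 6 when adjusted over the list alone (median log2 fold change 1.66, camera adjusted p = 1.9e-06; adjusted p = 0.711 with an estimated correlation). The small heat shock gene hspG2 rose from 4.98 ± 1.11 to 80.1 ± 5.81 CPM (4.01 ± 0.35, adjusted p = 0.000153) and hspC from 89.3 ± 12.8 to 652 ± 118 (2.87 ± 0.26, adjusted p = 0.000203). The 4 that fell, named after their values were seen, encode subunits of the cytosolic chaperonin, which folds actin and tubulin: cct8 (-1.31, adjusted p = 0.00673), cct7 (-1.09, adjusted p = 0.0263), tcp1 (-1.05, adjusted p = 0.00869) and cct3 (-0.87, adjusted p = 0.0167). The count of 4 became 2 without E. coli replicate 3 and 2 without S. salivarius replicate 2 or 3. Ribosome biogenesis genes, which process ribosomal RNA and assemble ribosomes, rose in 14 of 24 cases with 0 lower, 18 when adjusted over the list alone (median log2 fold change 2.41, camera adjusted p = 1.9e-06; adjusted p = 0.678 with an estimated correlation), and in 9, 8 and 9 cases without E. coli replicate 1, E. coli replicate 3 and S. salivarius replicate 3. mpp10, of the complex that processes small-subunit RNA (3.44 ± 0.47, adjusted p = 0.00104), and emg1, a ribosomal RNA methyltransferase gene (2.86 ± 0.38, adjusted p = 0.000955), were among them. Nucleotide synthesis genes rose in 12 of 23 cases with 0 lower, 12 when adjusted over the list alone (median log2 fold change 1.35, camera adjusted p = 2.55e-05; adjusted p = 0.302 with an estimated correlation), with purH of purine synthesis going from 54.2 ± 10.1 to 691 ± 70.3 CPM (3.67 ± 0.27, adjusted p = 8.23e-05) and prsA, a phosphoribosyl pyrophosphate synthetase gene, from 12.4 ± 1.16 to 65.2 ± 3.15 (2.39 ± 0.25, adjusted p = 0.000286). In the metal transport list, 4 of 12 genes rose and 0 fell, 4 when adjusted over the list alone (median log2 fold change 0.45, camera adjusted p = 0.0136; adjusted p = 0.361 with an estimated correlation): nramp1, the divalent metal transporter of phagosomes, went from 13.7 ± 4.39 to 78.5 ± 4.8 CPM (2.51 ± 0.28, adjusted p = 0.000395), and fhbB (2.31 ± 0.28, adjusted p = 0.000556) encodes a flavohaemoglobin, which breaks down nitric oxide and is no transporter. The other 2 were zntC, a zinc transporter gene (2.97, adjusted p = 0.00382), and mcfF, a mitochondrial carrier gene (2.94, adjusted p = 0.00232), named after their values were seen. On S. mutans 4 of the 12 metal transport genes also rose and 0 fell, though the list did not pass (median log2 fold change 0.57, camera adjusted p = 0.112).

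Lysosomal proteases were the list with the lowest median of the 12 that passed on S. salivarius: 8 of 11 fell and 1 rose, 8 and 3 when adjusted over the list alone (median log2 fold change -2.38, camera adjusted p = 2.55e-05; adjusted p = 0.133 with an estimated correlation). Besides cprF, ctsD, the cathepsin D gene, went from 2168 ± 195 to 417 ± 103 CPM (-2.38 ± 0.40, adjusted p = 0.00298), ctsB, the cathepsin B gene, from 514 ± 101 to 76.0 ± 14.4 (-2.76 ± 0.28, adjusted p = 0.000286) and cprG from 3439.9 ± 511 to 457 ± 144 (-2.91 ± 0.44, adjusted p = 0.00179). cprD fell (-2.89 ± 0.76, adjusted p = 0.0244), but passed no more when any 1 of the 6 libraries compared was left out (adjusted p of 0.0504, 0.0574 and 0.0603 without E. coli replicates 1, 2 and 3, and of 0.0580, 0.0956 and 0.0644 without S. salivarius replicates 1, 2 and 3). The member that rose was cprA, a cysteine proteinase gene switched on during development (6.03, adjusted p = 0.00409; named after its values were seen). The count of 1 became 2 without S. salivarius replicate 1, S. mutans replicate 1 or S. mutans replicate 2. Other large falls were in V4-7 (from 974 ± 154 to 82.0 ± 21.2 CPM, -3.57 ± 0.52), cf45-1, a counting factor gene that limits group size (from 765 ± 8.88 to 53.0 ± 16.4 CPM, -3.85 ± 0.56, adjusted p = 0.00151), ranB, a Ran GTPase gene (-2.98 ± 0.31), and adprt1B, of the poly(ADP-ribose) polymerase family (-2.81 ± 0.29). comF-1 and comF-2, also among the largest falls, passed no more without S. salivarius replicate 3 (adjusted p = 0.0507 and 0.0538).

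Density-sensing factors fell in 4 of 14 cases with 0 higher, 5 lower and 1 higher when adjusted over the list alone (median log2 fold change -1.22, camera adjusted p = 0.00267; adjusted p = 0.622 with an estimated correlation), and in 7 cases without S. mutans replicate 2. Beside cf45-1, the counting factor gene cf50-2 fell (-1.63 ± 0.35, adjusted p = 0.00999), as did its copy cf50-1 and cfaD, a secreted repressor of proliferation (-1.25, adjusted p = 0.0138), the last pair named after their values were seen. Actin cytoskeleton genes fell in 12 of 83 cases and rose in 6, 14 and 7 when adjusted over the list alone (median log2 fold change -0.48, camera adjusted p = 0.000867; adjusted p = 0.711 with an estimated correlation), with act10, an actin gene, going from 2402 ± 486 to 647 ± 61.0 CPM (-1.89 ± 0.29, adjusted p = 0.00202) and hatB, a hisactophilin gene, from 7105 ± 1952 to 1021 ± 426 (-2.80 ± 0.43, adjusted p = 0.00193). The 12 falls became 6, 4, 3, 3 and 22 without E. coli replicate 2, E. coli replicate 3, S. salivarius replicate 2, S. salivarius replicate 3 and S. mutans replicate 1. Genes of the TCA cycle, the mitochondrial pathway that oxidises acetyl groups, fell in 5 of 30 cases with 0 higher, 9 when adjusted over the list alone (median log2 fold change -0.44, camera adjusted p = 0.00788; adjusted p = 0.622 with an estimated correlation). The 5 became 3, 1, 0, 2, 0, 0 and 10 without E. coli replicates 1, 2 and 3, S. salivarius replicates 1, 2 and 3 and S. mutans replicate 1. pdhC, of the pyruvate dehydrogenase complex (-0.98 ± 0.25, adjusted p = 0.0199), passed no more without E. coli replicate 2 or 3 or S. salivarius replicate 2 or 3 (adjusted p = 0.0665, 0.0769, 0.0876 and 0.0537), and idhC, an isocitrate dehydrogenase gene (-1.0 ± 0.25, adjusted p = 0.019), without E. coli replicate 1 or 3 or S. salivarius replicate 2 or 3 (0.0541, 0.0617, 0.0852 and 0.0565). The other members that fell, named after their values were seen, were scsA (-0.86, adjusted p = 0.0286), pdhA (-0.85, adjusted p = 0.0311) and odhA (-1.19, adjusted p = 0.0449), genes of succinyl-CoA synthetase, pyruvate dehydrogenase and oxoglutarate dehydrogenase.

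No single cytosolic ribosomal protein gene of 79 passed in edgeR with all 9 libraries fitted together, over all genes or when adjusted over the list alone, while the list as a set lay lower (median log2 fold change -0.80, camera adjusted p = 3.85e-05; adjusted p = 0.879 with an estimated correlation), and fry did not call it (adjusted p = 0.407). The count of 0 was not stable: 38 were lower when only the 6 libraries compared were fitted, 42 in limma-voom with library quality weights (chosen after seeing the data), 26 without S. mutans replicate 1 and 2 without E. coli replicate 1. The 2 members with the smallest p, rpl16 (-2.04 ± 0.74, adjusted p = 0.0754) and rpl2 (-2.08 ± 0.92, adjusted p = 0.137), are encoded in the mitochondrion; they passed without E. coli replicate 1 (adjusted p = 0.0314 and 0.0232), and rpl16 also without S. mutans replicate 1 (0.025). Among genes followed in every comparison, catA, a catalase gene (-0.52 ± 0.24, adjusted p = 0.156), alyA, a lysozyme gene (-1.23 ± 0.60, adjusted p = 0.167), and cotB, a spore coat gene (1.43 ± 1.31, adjusted p = 0.469), did not pass. None of the 12 list calls held with a correlation between genes estimated from these data. With fry, 11 of the 12 passed in the same direction. Of genes changed by log2 sizes of 1 and 2 in simulated data, the edgeR test called 5% and 54%. Those data held 200 changed genes, against 2122 called here, and the adjustment is stricter where fewer genes change. Real 2-fold changes can be missed, but the simulated data cannot say what share of them.

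**Figure D2:**
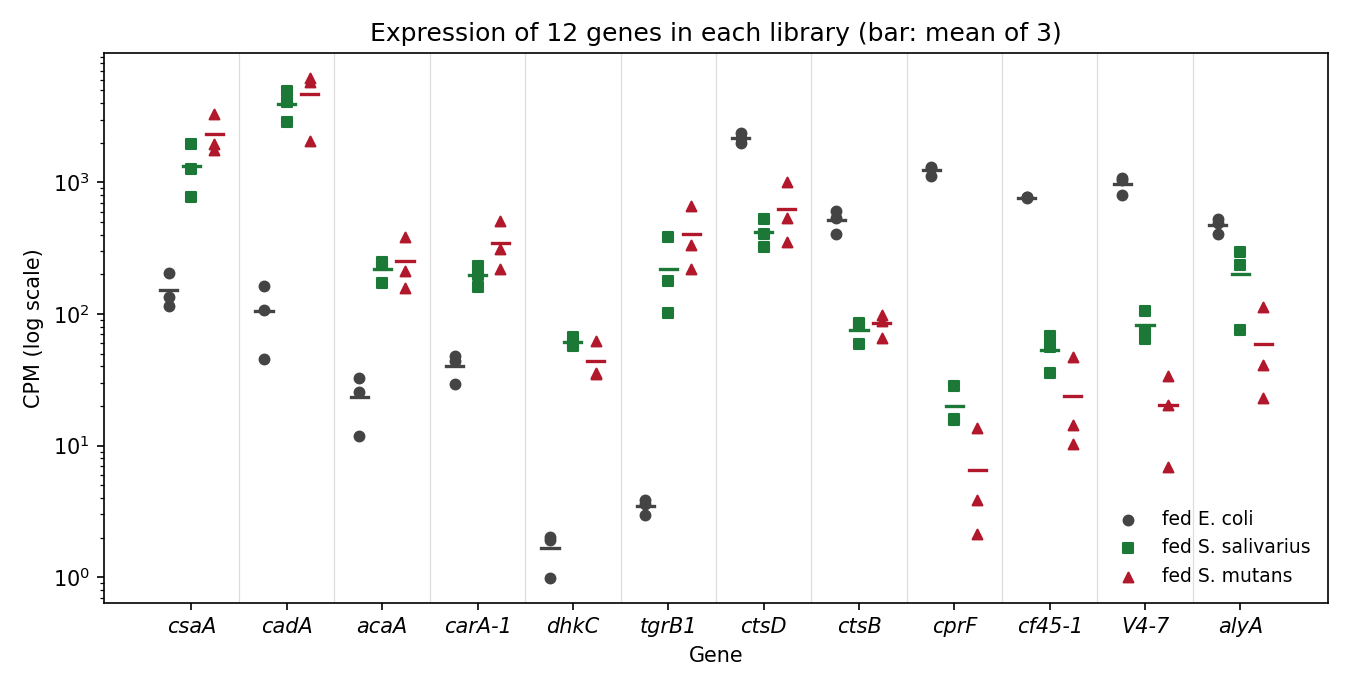
Each point is the expression of 1 gene in 1 library (vertical axis, CPM on a log scale) for 12 genes (horizontal axis), with circles for E. coli, squares for S. salivarius and triangles for S. mutans and a bar at each mean of 3. csaA, cadA, acaA, carA-1, dhkC and tgrB1 are higher in all 6 libraries on streptococci than in all 3 on E. coli, and ctsD, ctsB, cprF, cf45-1 and V4-7 are lower in all 6.

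On S. mutans, 21 of 27 early development genes were higher than on E. coli, while 8 of 11 lysosomal protease genes (2 higher), 33 of 79 ribosomal protein genes and 15 of 30 TCA cycle genes (1 higher) were lower. As sets these 4 lists passed in camera with its preset correlation but not with an estimated one (adjusted p = 0.243, 0.243, 0.692 and 0.62), and the 33 became 1 to 77 when single libraries were left out. csaA averaged 2338 ± 849 CPM on S. mutans against 152 ± 47.0 on E. coli (3.94 ± 0.46, adjusted p = 0.000469), and cprF 6.53 ± 6.21 against 1234.3 ± 105 (-7.56 ± 0.75, adjusted p = 0.000295). In all, 1706 genes were higher and 1085 lower. The share of called genes that were higher, 61.1%, was 50.3% with upper-quartile scaling and 84.4% when scaled to library size alone, where the median of all genes was 0.67, against 0.10 with the main scaling. The count of 2791 genes became 1652 without E. coli replicate 3 and 1845 without S. mutans replicate 2.

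Of the 27 early development genes, 21 rose and 0 fell, 21 when adjusted over the list alone (median log2 fold change 2.51, camera adjusted p = 1.69e-13; adjusted p = 0.243 with an estimated correlation), with tgrB1 (6.86 ± 0.65, adjusted p = 0.000247), dhkC (4.74 ± 0.38, adjusted p = 0.000168), acaA (3.42 ± 0.46, adjusted p = 0.000943) and carA-1 (3.09 ± 0.36, adjusted p = 0.000503) among them. cadA averaged 4675 ± 2264 CPM (5.47 ± 0.63). Without S. mutans replicate 1, 1 member of the list was lower. All 7 discoidin genes rose, and all 7 when adjusted over the list alone (median log2 fold change 2.25, camera adjusted p = 6.19e-06; adjusted p = 0.62 with an estimated correlation), including dscE (2.59 ± 0.33, adjusted p = 0.000755) and dscA-1, at 4863 ± 1238 CPM (2.41 ± 0.38). In the Tgr family 9 of 11 members rose and 0 fell, 9 when adjusted over the list alone (median log2 fold change 6.86, camera adjusted p = 5.2e-07; adjusted p = 0.62 with an estimated correlation), the median being 5.07 with the 4 few-count members at their bound, and tgrR1 went from 4.94 ± 1.58 to 166 ± 49.4 CPM (5.07 ± 0.47, adjusted p = 0.000225). Prestalk markers, genes of the cells that form the stalk, rose in 7 of 16 cases with 0 lower, 7 when adjusted over the list alone (median log2 fold change 1.03, camera adjusted p = 0.0146; adjusted p = 0.641 with an estimated correlation), and the list passed no more without E. coli replicate 1 (adjusted p = 0.0571). On S. salivarius 7 of the 16 also rose and 1 fell, though the list did not pass (median log2 fold change 0.86, camera adjusted p = 0.225). On S. mutans tagB, a prestalk gene with protease and transporter domains, went from 2.61 ± 0.647 to 80.7 ± 48.8 CPM (4.95 ± 0.74, adjusted p = 0.00146), and gtaC, a GATA transcription factor gene of early development, from 54.6 ± 3.26 to 149.8 ± 39.2 (1.46 ± 0.24, adjusted p = 0.00235). The spore coat gene cotB rose (5.20 ± 1.46, adjusted p = 0.025), a call that ended without E. coli replicate 2 (adjusted p = 0.0783), E. coli replicate 3 (0.0896) or S. mutans replicate 2 (0.0714).

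The largest rises again held genes at or near 0 counts on E. coli: against the floor of 3 counts over the group, cbpC was at least 2210-fold higher and limA at least 1399-fold. cbpF, at 3 counts on E. coli, had a ratio of 4742 (95% counting interval 1623 to 22993). phdA went from 0.760 ± 0.408 to 908 ± 572 CPM (10.22 ± 1.1, adjusted p = 0.000376). cmbC (11.94 ± 1.63), nagD (10.79 ± 1.56) and psiA, which encodes a secreted inducer of prespore cells (10.77 ± 2.30), were also among the largest, with psiA at 164 ± 254 CPM. limA, nagD and psiA passed no more in limma-voom (adjusted p = 0.0732, 0.0600 and 0.266), and on S. salivarius the same held of limA, cmbC and nagD (0.160, 0.0745 and 0.123).

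Cytosolic ribosomal protein genes fell in 33 of 79 cases with 0 higher, 72 when adjusted over the list alone (median log2 fold change -1.82, camera adjusted p = 2.45e-17; adjusted p = 0.692 with an estimated correlation). rps29 went from 1503 ± 373 to 242 ± 217 CPM (-2.64 ± 0.60, adjusted p = 0.00999) and rpl4 from 8146 ± 1907 to 1882 ± 1458 (-2.11 ± 0.55, adjusted p = 0.0185). S. mutans replicate 1, with 23.5% of counts in these genes, stood apart from replicates 2 and 3 (6.60% and 10.2%). The 33 became 5, 13 and 3 without E. coli replicates 1, 2 and 3, 18, 22 and 18 without S. salivarius replicates 1, 2 and 3, and 77, 12 and 1 without S. mutans replicates 1, 2 and 3, where the shared estimate of the spread changes too. It was 4 when only the 6 libraries compared were fitted, 69 in DESeq2 and 70 in limma-voom. rpl4 passed no more without E. coli replicate 1 (adjusted p = 0.0543) or S. mutans replicate 3 (0.0565).

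Ribosome biogenesis genes moved the other way, 16 of 24 being higher and 0 lower, 19 when adjusted over the list alone (median log2 fold change 2.73, camera adjusted p = 8.81e-06; adjusted p = 0.692 with an estimated correlation), with 10 higher without E. coli replicate 3 and 9 without S. mutans replicate 3. mpp10 (3.51 ± 0.47, adjusted p = 0.000939) and emg1 (3.06 ± 0.38, adjusted p = 0.000713) rose. Of 32 heat shock and chaperone genes, 17 rose and 7 fell, 17 and 10 when adjusted over the list alone (median log2 fold change 1.31, camera adjusted p = 0.0198; adjusted p = 0.799 with an estimated correlation); the 7 falls became 4 without E. coli replicate 3 and 12 without S. mutans replicate 1, without which the list did not pass (adjusted p = 0.181), as with fry (0.0751). hspG2 (3.28 ± 0.34, adjusted p = 0.000317) and hspC (2.83 ± 0.26, adjusted p = 0.000222) rose, while the chaperonin genes cct8 (-1.72, adjusted p = 0.00162) and cct7 (-1.40, adjusted p = 0.00738), named after their values were seen, fell.

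In the TCA cycle 15 of 30 genes fell and 1 rose, 19 and 1 when adjusted over the list alone (median log2 fold change -0.86, camera adjusted p = 5.81e-05; adjusted p = 0.62 with an estimated correlation). The isocitrate dehydrogenase genes idhA, from 173 ± 19.9 to 39.9 ± 15.6 CPM (-2.12 ± 0.37, adjusted p = 0.0031), and idhC, from 548 ± 67.8 to 148 ± 30.9 (-1.89 ± 0.26, adjusted p = 0.000954), were among them; mdhC, a malate dehydrogenase gene named after its values were seen, rose (0.87, adjusted p = 0.0497), and the count of 1 became 0 without any library but S. mutans replicate 1. The 15 became 7, 6, 8, 7 and 8 without E. coli replicate 2, E. coli replicate 3, S. salivarius replicate 3, S. mutans replicate 2 and S. mutans replicate 3. Nuclear genes of oxidative phosphorylation fell in 4 of 25 cases with 0 higher, 4 when adjusted over the list alone (median log2 fold change -0.40, camera adjusted p = 0.0198; adjusted p = 0.702 with an estimated correlation), with atp5b, the ATP synthase beta subunit gene (-1.40 ± 0.33, adjusted p = 0.0122), uqcrh, of respiratory complex III (-1.1 ± 0.28, adjusted p = 0.0174), and, named after their values were seen, ndufv1 and cyc1, while the median of the list was 0.15 when scaled to library size alone. That list passed no more without E. coli replicate 2 (adjusted p = 0.0870), without E. coli replicate 3 (0.0655) or with fry (0.112), its 4 falls became 2 without E. coli replicate 3 and 1 without S. mutans replicate 2, and uqcrh passed no more without E. coli replicate 1 or S. mutans replicate 2 (0.0555 for each). Beta-oxidation and peroxisome genes fell in 2 of 25 cases, 1 when adjusted over the list alone (median log2 fold change -0.53, camera adjusted p = 0.0198; adjusted p = 0.692 with an estimated correlation): masA (-1.68 ± 0.27, adjusted p = 0.00206) and catA (-0.76 ± 0.24, adjusted p = 0.0424). That list passed no more without S. mutans replicate 3 (camera adjusted p = 0.0650). Its 2 falls became 10 without S. mutans replicate 1, 3 without E. coli replicate 1 and 1 without any other library. Over all 9938 tested genes 1085 were lower on S. mutans, a larger share than 2 of 25. When single libraries were left out, catA still passed without S. mutans replicate 1 alone, with an adjusted p of 0.0564 to 0.127 without any other.

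Lysosomal proteases fell in 8 of 11 cases and rose in 2, 8 and 3 when adjusted over the list alone (median log2 fold change -1.78, camera adjusted p = 0.000278; adjusted p = 0.243 with an estimated correlation). ctsB averaged 84.7 ± 16.9 CPM against 514 ± 101 (-2.60 ± 0.28, adjusted p = 0.000376), ctsD fell (-1.78 ± 0.39, adjusted p = 0.00863), and cprD fell (-3.01 ± 0.77, adjusted p = 0.017) except without S. mutans replicate 3 (adjusted p = 0.0561). The 2 that rose were cprA (7.30, adjusted p = 0.00181) and cprB (7.48, adjusted p = 0.00539), cysteine proteinase genes of development, named after their values were seen. The lysozyme gene alyA fell from 476 ± 61.4 to 59.1 ± 47.9 CPM (-3.01 ± 0.63, adjusted p = 0.00738) and nramp1 rose to 37.1 ± 0.571 CPM (1.44 ± 0.27, adjusted p = 0.00422). Density-sensing factors fell in 7 of 14 cases and rose in 2, 7 and 2 when adjusted over the list alone (median log2 fold change -1.40, camera adjusted p = 0.0022; adjusted p = 0.62 with an estimated correlation), with cf45-1 (-5.00 ± 0.59, adjusted p = 0.000524) and cfaD (-1.58 ± 0.29, adjusted p = 0.004). The 2 that rose, bzpN, a bZIP transcription factor gene (1.71, adjusted p = 0.0153), and grlH, a receptor gene (2.83, adjusted p = 0.0419), were named after their values were seen; the count was 1 without E. coli replicate 1, any S. salivarius library, S. mutans replicate 2 or S. mutans replicate 3, and 0 without E. coli replicate 2 or 3. Actin cytoskeleton genes fell in 13 of 83 cases and rose in 7, 11 and 7 when adjusted over the list alone (median log2 fold change -0.43, camera adjusted p = 0.0258; adjusted p = 0.702 with an estimated correlation), while the median was 0.18 when scaled to library size alone. hatB (-3.54 ± 0.44, adjusted p = 0.000707) and act10 (-1.67 ± 0.29, adjusted p = 0.0031) fell. That list passed no more without E. coli replicate 3 (adjusted p = 0.0669), S. mutans replicate 1 (0.0818) or S. mutans replicate 3 (0.0650), nor with fry (0.121); its 13 falls became 8, 8, 5, 8, 21 and 5 without E. coli replicates 1, 2 and 3, S. salivarius replicate 3 and S. mutans replicates 1 and 3, and its 7 rises became 4 without E. coli replicate 2.

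Other large falls were V4-7, from 974 ± 154 to 20.2 ± 13.3 CPM (-5.59 ± 0.57, adjusted p = 0.000312), stlA, a polyketide synthase gene, from 212 ± 43.2 to 15.1 ± 10.5 (-3.81 ± 0.65, adjusted p = 0.00271), comF-2 (-4.11 ± 0.68), DG1041 (-3.95 ± 0.51) and cad3, from 18.3 ± 5.26 to 0.917 ± 0.701 (-4.34 ± 0.71). In simulated data the test called 4% of genes changed by a log2 size of 1 and 51% of those changed by 2. Those data held 200 changed genes, against 2791 called here, so these shares need not hold for the real comparison. None of the 13 list calls held with an estimated correlation. With fry, 10 of the 13 passed in the same direction.

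**Figure D3:**
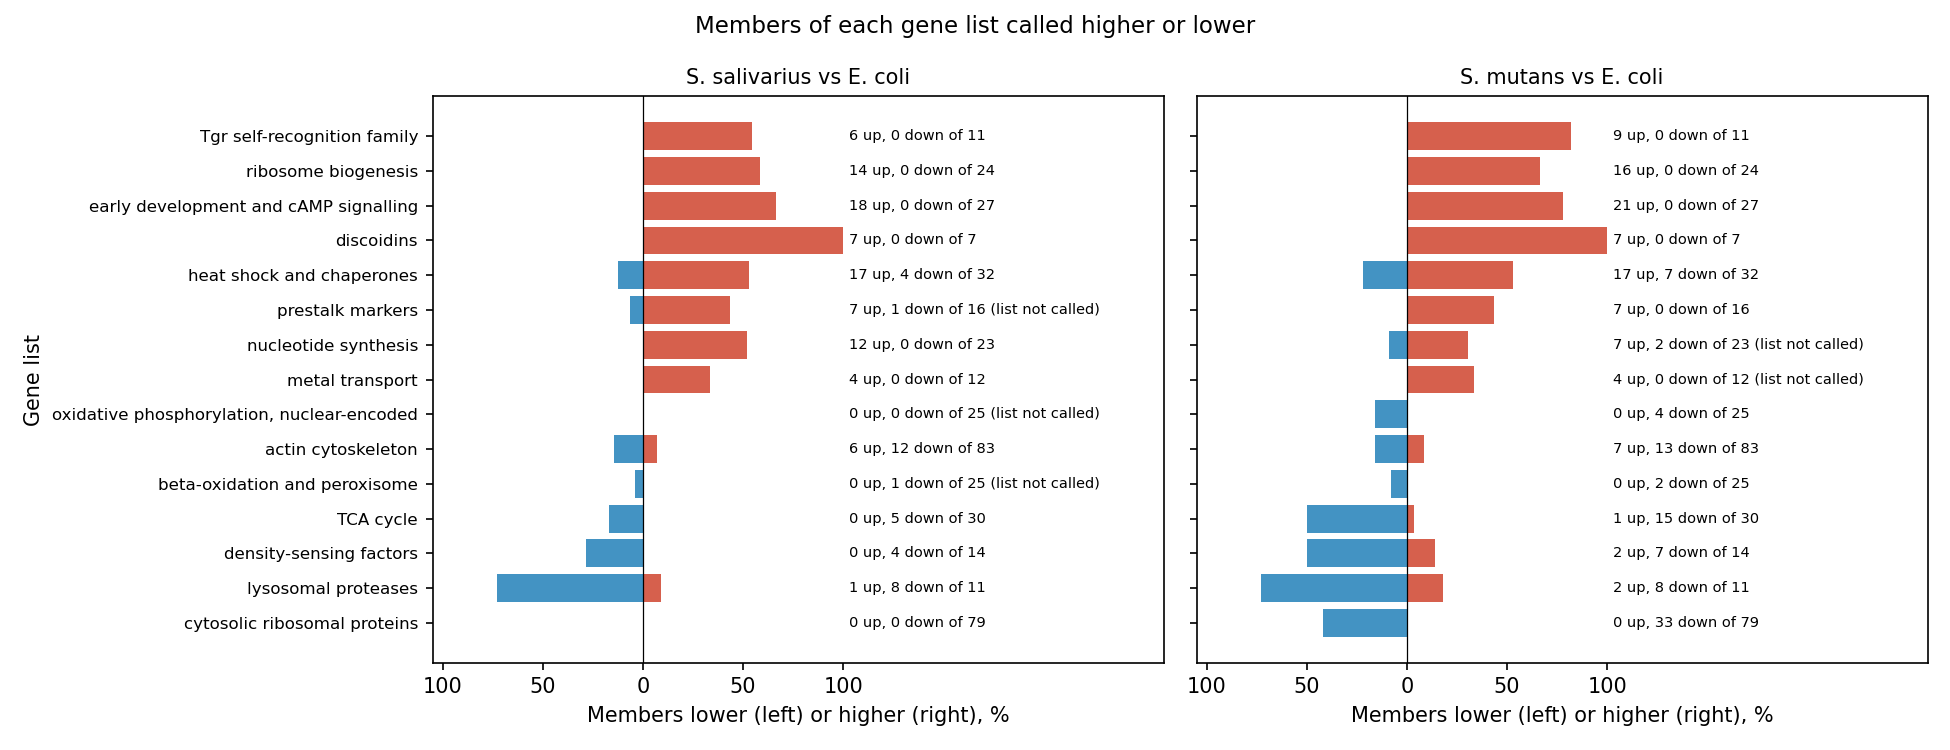
Bars give the percent of tested members of each gene list (vertical axis) that were lower (left) or higher (right) on S. salivarius (left panel) and on S. mutans (right panel) than on E. coli, with the counts in text. All 7 discoidins and 18 and 21 of 27 early development genes were higher, and 8 of 11 lysosomal proteases were lower in each panel.

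The responses to both streptococci were compared gene by gene. Of the called genes, 1075 were higher on both and 554 lower on both, 1629 in all, 1 went in opposite directions, 492 were called on S. salivarius alone and 1161 on S. mutans alone. Independent lists of these sizes would share 230.2 higher and 85.3 lower genes. A gene called in 1 comparison alone is not thereby shown to differ between the streptococci. The larger count on S. mutans (2791 against 2122) also reversed when only the 6 libraries compared were fitted, with 1948 genes against 2954 on S. salivarius. The gene in opposite directions, DDB_G0271892, named after its values were seen, had log2 fold changes of 0.89 and -0.75. Across the 9938 tested genes, which are not independent replicates, the log2 fold changes had a covariance of 2.97 and a correlation of 0.897, against 0.239 (0.223 to 0.25) and 0.543 (0.521 to 0.563) in 20 simulations of unchanged groups set against the same 3 E. coli libraries, and 83.3% of genes had the same sign against 67.2%. Both comparisons use those 3 libraries, which are too few to be divided between them, so part of the excess covariance of 2.73 may rest on what they share. The simulations drew each library on streptococci independently, so deviations shared by S. salivarius and S. mutans libraries of the same number, which would also raise the covariance, are not in the simulated values. The 1629 genes became 918 without E. coli replicate 3, 939 without S. salivarius replicate 2 and 992 without S. salivarius replicate 3, and the 1 gene in opposite directions became 67 genes without S. mutans replicate 1 and 0 without any other library.

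Between the streptococci, no gene passed in edgeR, though 1231 of the 9938 had an unadjusted p under 0.05. DESeq2 called 313 genes (211 higher on S. salivarius and 102 lower) and limma-voom 18 (17 and 1). Without S. mutans replicate 1, the library that lay nearest the S. salivarius libraries, edgeR called 1574 genes, 918 higher and 656 lower on S. salivarius, and without any other library it called 0. Leaving out the library of a group that lies nearest the other group tends by itself to widen the difference and narrow the spread. Values without S. mutans replicate 1, here and below, are therefore no independent support for a difference. The gene with the smallest adjusted p among those named, alrE, an aldehyde reductase gene, averaged 127 ± 19.5 CPM on S. salivarius and 21.6 ± 10.1 on S. mutans (2.55 ± 0.41, adjusted p = 0.079; 3.01 ± 0.38, adjusted p = 0.00285 without S. mutans replicate 1). nramp1 averaged 78.5 ± 4.8 CPM against 37.1 ± 0.571 (1.08 ± 0.27, adjusted p = 0.185; 1.07 ± 0.29, adjusted p = 0.0343 without that library). In simulated data the test called 1% of genes changed by a log2 size of 1 and 46% of those changed by 2.

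As sets, 15 lists differed in camera, 9 higher and 6 lower on S. salivarius, and none held with an estimated correlation (adjusted p of 0.436 to 0.678) or with fry. Members passing over a list alone, below, were not adjusted over the lists, and no gene passed over all genes with all 9 libraries in edgeR. Cytosolic ribosomal protein genes lay higher on S. salivarius (median log2 fold change 0.97, camera adjusted p = 7.19e-21; adjusted p = 0.543 with an estimated correlation), with rps29 at 644 ± 195 CPM against 242 ± 217 (1.41 ± 0.57, adjusted p = 0.362) and 0 of 79 called, over all genes or when adjusted over the list alone. Without S. mutans replicate 1, in which these genes took 23.5% of counts, 74 of the 79 passed (rps29 2.45 ± 0.40, adjusted p = 0.00489). DNA replication and cell cycle genes also lay higher (median log2 fold change 0.65, camera adjusted p = 3.89e-08; adjusted p = 0.461 with an estimated correlation), 4 of 47 passing when adjusted over the list alone (mcm6, cdc45, rfc3 and top2, the last pair named after their values were seen), with mcm6, of the replicative helicase, at 13.2 ± 3.11 CPM against 3.67 ± 1.13 (1.85 ± 0.32, adjusted p = 0.109), and cdc45, of a protein that joins that helicase in its active form, at 2.54 ± 1.09 against 0.420 ± 0.239 (2.60 ± 0.58, adjusted p = 0.154). Nucleotide synthesis (median log2 fold change 0.75, camera adjusted p = 6.92e-07; adjusted p = 0.436 with an estimated correlation), with 1 of 23, purC/E of purine synthesis, passing over the list alone, and heat shock genes (median log2 fold change 0.62, camera adjusted p = 2.03e-06; adjusted p = 0.543 with an estimated correlation), with 0 of 32, lay higher too. Without S. mutans replicate 1, 6, 7 and 9 members of these 3 lists passed.

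Discoidins lay higher on S. salivarius (median log2 fold change 1.08, camera adjusted p = 4.11e-06; adjusted p = 0.461 with an estimated correlation), 6 of 7 passing when adjusted over the list alone and 6 over all genes without S. mutans replicate 1, with dscA-1 at 12105 ± 3390.3 CPM against 4863 ± 1238 (1.32 ± 0.37, adjusted p = 0.228). Lysozymes (median log2 fold change 0.69, camera adjusted p = 0.00049; adjusted p = 0.436 with an estimated correlation) lay higher, 2 of 6 (alyA and alyC) passing over the list alone, with alyA at 202 ± 113 CPM against 59.1 ± 47.9 (1.77 ± 0.61, adjusted p = 0.303; 2.66 ± 0.54, adjusted p = 0.0109 without S. mutans replicate 1). Oxidative stress genes (median log2 fold change 0.32, camera adjusted p = 0.000419; adjusted p = 0.461 with an estimated correlation) had 6 of 25 higher over the list alone, among them alrE and alrA, both of aldehyde reductases (2.1 ± 0.47, adjusted p = 0.154 for alrA), and the list passed no more without S. salivarius replicate 1 (adjusted p = 0.0726). The TCA cycle (median log2 fold change 0.18, camera adjusted p = 0.00461; adjusted p = 0.461 with an estimated correlation) and glycolysis (median log2 fold change 0.31, camera adjusted p = 0.0146; adjusted p = 0.461 with an estimated correlation) lay higher, with medians of -0.11 and -0.01 when scaled to library size alone, and 0 members of either passed over the list alone. Among their members with the smallest p were idhC (0.89 ± 0.25, adjusted p = 0.228) and the glycolytic gene gpi (0.91 ± 0.26, adjusted p = 0.228). Without S. mutans replicate 1, 6 TCA cycle, 3 glycolysis, 5 lysozyme and 10 oxidative stress genes passed over all genes as higher, and 2 oxidative stress genes as lower.

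Prespore and spore markers, genes of the cells that become spores, lay lower on S. salivarius than on S. mutans (median log2 fold change -1.47, camera adjusted p = 0.00044; adjusted p = 0.436 with an estimated correlation), with 0 of 15 passing over the list alone: cotB averaged 1.45 ± 1.81 CPM against 19.9 ± 20.7 (-3.77 ± 1.34, adjusted p = 0.316; -4.33 ± 1.05, adjusted p = 0.0227 without S. mutans replicate 1) and pspB 9.60 ± 2.81 against 30.3 ± 22.7 (-1.66 ± 0.54, adjusted p = 0.288). Prestalk markers lay lower (median log2 fold change -0.66, camera adjusted p = 0.00846; adjusted p = 0.461 with an estimated correlation), 0 of 16 passing over the list alone, with cprB at 6.09 ± 6.34 CPM against 125 ± 166 (-4.36 ± 1.26, adjusted p = 0.241). So did the Tgr family (median log2 fold change -0.94, camera adjusted p = 0.000183; adjusted p = 0.461 with an estimated correlation; 1 of 11, tgrM1, over the list alone), with tgrM1 at 1.77 ± 1.26 against 9.78 ± 6.54 (-2.47 ± 0.64, adjusted p = 0.194), G protein-coupled receptors (median log2 fold change -0.64, camera adjusted p = 0.00143; adjusted p = 0.436 with an estimated correlation; 2 of 34, the copies fslJ-1 and fslJ-2), calcium-upregulated proteins (median log2 fold change -0.74, camera adjusted p = 0.0362; adjusted p = 0.678 with an estimated correlation; 0 of 9) and the phagocytosis and endosome machinery (median log2 fold change -0.24, camera adjusted p = 0.0362; adjusted p = 0.588 with an estimated correlation; 1 of 53, racF1, a Rac GTPase gene named after its values were seen and higher on S. salivarius). The phagocytosis call ended with the replicate number as a block (adjusted p = 0.0566) and without E. coli replicate 1 (0.0652), 2 (0.0537) or 3 (0.0559), S. salivarius replicate 2 (0.143) or 3 (0.0898) or S. mutans replicate 2 (0.0589), and that of calcium-upregulated proteins without S. salivarius replicate 3 (0.124) or S. mutans replicate 2 (0.0517) or 3 (0.292). Without S. mutans replicate 1, 10 receptor genes passed over all genes as lower on S. salivarius and 1 as higher, and 9 and 2 of the phagocytosis list. In that fit 4 prestalk markers (0 higher), 3 prespore and spore markers (1 higher), 3 Tgr genes (0 higher) and 2 calcium-upregulated genes (0 higher) were lower. The 15 lists became 24 without S. mutans replicate 3. The early development list, with a median of -0.26, did not pass (camera adjusted p = 0.0506) but did with the block (0.0206). Single genes of it, csaA (-0.82 ± 0.41, adjusted p = 0.454), carA-1 (-0.81 ± 0.34, adjusted p = 0.379), acaA (-0.19 ± 0.42, adjusted p = 0.882) and cadA (-0.24 ± 0.52, adjusted p = 0.88), were not shown to differ between the streptococci, nor were the protease genes ctsD (-0.60 ± 0.38, adjusted p = 0.539) and cprD (0.12 ± 0.71, adjusted p = 0.961) or catA (0.24 ± 0.24, adjusted p = 0.732).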

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

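Library-size scaling, library quality weights, corrected lists, leaving out E. coli replicate 1 and S. mutans replicate 1 together, and the block on only the 6 libraries compared were chosen after seeing the data. The count of genes changed on S. salivarius against E. coli, 2122, lay between 1929 and 2954 under other tools, scalings, filters, designs and effect sizes, ranged from 1101 to 3061 when single libraries were left out (lowest without S. salivarius replicate 2, also 1165 without E. coli replicate 3 and 1160 without S. salivarius replicate 3), and was 5241 with quality weights. On S. mutans against E. coli, 2791 ranged from 1652 (without E. coli replicate 3; 1845 without S. mutans replicate 2) to 3955 when single libraries were left out, from 1224 (the block on only the 6 libraries compared; 1948 the next lowest) to 3589 under those, was 4096 with both of E. coli replicate 1 and S. mutans replicate 1 out and 4889 with quality weights. Between the streptococci the count of 0 was 313 with DESeq2, 18 with limma-voom, 3 without a filter, 2 with library-size scaling, 0 to 1574 when single libraries were left out (1574 without S. mutans replicate 1), 2172 with E. coli replicate 1 out as well and 2682 with quality weights, which gave S. mutans replicate 1 a weight of 0.178 and E. coli replicate 1 one of 0.284. The genes shared by both responses, 1629, ranged from 918 to 2075 when single libraries were left out (939 and 992 without S. salivarius replicates 2 and 3) and from 1459 (absolute log2 fold change of at least 1) to 2236 (DESeq2) under the other settings. The cause was not tested for these, except that fewer libraries leave fewer degrees of freedom.

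Lists called against E. coli, 12 and 13, ranged from 12 to 15 and from 11 to 15 when single libraries were left out, and the 15 between the streptococci from 13 to 24 (24 without S. mutans replicate 3). With library-size scaling, 10 lists passed on S. mutans against E. coli, all among the 13. Between the streptococci 15 passed with that scaling, 13 of them among the main 15. Cytosolic ribosomal protein genes lower on S. salivarius, 0 of 79, became 38 with only the 6 libraries compared, 50 with the block on those 6 and 42 with quality weights; the 33 on S. mutans became 4, 12 and 79. With the block on those 6, discoidins higher on S. mutans went from 7 to 3 of 7 and lysosomal proteases lower from 8 to 5 of 11. With an estimated correlation 0 lists passed in each comparison; with fry, 14 and 17 passed against E. coli and 0 between the streptococci, where 9 had an unadjusted p under 0.05. Of the values of named genes under alternatives, 1020 of 1053 on S. salivarius and 1044 of 1078 on S. mutans kept direction and call, as did 735 of 855 between the streptococci. Direction reversed for cotB on S. salivarius (1.43, from -0.37 to 2.74 without single libraries, lowest without S. salivarius replicate 2) and, between the streptococci, for genes that did not pass in those settings: catA (0.24; -0.049 with library-size scaling), cprD (0.12; from -0.37 to 1.36 without single libraries, with -0.08 without S. salivarius replicate 1, -0.07 without S. salivarius replicate 3, -0.37 without S. mutans replicate 2, -0.07 without S. mutans replicate 3 and -0.0071 with library-size scaling, and a call in limma-voom with quality weights alone, adjusted p = 0.0415), acaA (-0.19; from -0.43 to 0.25 without single libraries, 0.25 without S. mutans replicate 1 and with quality weights, 0.22 with both libraries out) and cadA (-0.24; from -0.59 to 0.031, highest without S. mutans replicate 2). The cause was not tested.

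With the replicate number as a block, the counts were 2043, 2694 and 0 genes, 1619 shared genes and 12, 13 and 15 lists. On only the 6 libraries compared, the block gave 2340, 1224 and 0 genes and 12, 10 and 13 lists. Of these lists, 12, 9 and 12 were among the 12, 13 and 15 called in the main fit, so some list calls ended. The cause of the lower count of genes on S. mutans was not tested. Fitted on all 9 libraries, the block ended the call of the phagocytosis list between the streptococci (adjusted p = 0.0566) and made that of early development genes (0.0206). In that fit the block changed no other call of a list or named gene in that comparison. Against E. coli, where the numbers were not read as pairs, heat shock genes on S. mutans (0.0794) no longer passed, prespore markers did (0.00573), and cotB did not (0.107) nor catA (0.0510). In all, 6 of the 9 libraries correlated best with a library of their own number, a hint from the data and not from the design, for which no chance level was computed. Depth limits genes near the floor of 3 counts over a group.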

Other observations

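Tests given here that were chosen only after the result was seen are those of ribosomal protein reads (library-size scaling included) and of food shortage for the early development genes, the medians of that list without E. coli replicate 1, the random lists for all but prespore and spore markers, the level of nramp1 in S. mutans replicate 1, the change of other named genes without that library, and the counts in the Cbp and cytochrome P450 gene lists.

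Several lists that did not pass as sets against E. coli held genes that moved strongly, chosen here after their values were seen and given as log2 fold changes with adjusted p from edgeR. Over all 9938 tested genes, 1341 were higher and 781 lower on S. salivarius, and 1706 and 1085 on S. mutans. A count of called members near those shares says nothing about its list. In the phagocytosis and endosome list (camera adjusted p = 0.0505 on S. salivarius and 0.509 on S. mutans; of 53 genes, 5 higher and 13 lower on S. salivarius, 7 and 5 on S. mutans), racF1, a Rac GTPase gene, rose (4.94, adjusted p = 8.23e-05 on S. salivarius; 2.57, adjusted p = 0.000713 on S. mutans), as did vacB, a vacuolin gene (2.58, adjusted p = 0.00673; 2.64, adjusted p = 0.00494), and sibC, of the integrin-like Sib proteins (1.28, adjusted p = 0.0438; 2.21, adjusted p = 0.00398), while the retromer genes vps26 (-1.17, adjusted p = 0.0185; -1.26, adjusted p = 0.0108) and vps35 (-0.94, adjusted p = 0.0185; -0.89, adjusted p = 0.0187) fell. In nitrogen and amino acid metabolism (0.167 and 0.0880; of 29, 4 higher and 6 lower, then 5 and 10), the glutamine synthetase genes glnA1 (2.87, adjusted p = 0.01; 4.14, adjusted p = 0.00182) and glnA3 (2.13, adjusted p = 0.0015; 1.44, adjusted p = 0.0073) rose, and gcvT, of glycine cleavage (-1.53, adjusted p = 0.00232; -1.36, adjusted p = 0.00331), and mccB, of leucine breakdown (-1.04, adjusted p = 0.0064; -1.12, adjusted p = 0.00377), fell. Among prespore and spore markers (0.787 and 0.0880; of 15, 4 higher and 2 lower, then 6 and 1), the spore coat gene cotA (6.37, adjusted p = 0.0196; 7.86, adjusted p = 0.00594), the transcription factor gene srfA (5.72, adjusted p = 0.00687; 8.34, adjusted p = 0.00142) and carC, a cAMP receptor gene of later stages (7.04, adjusted p = 0.00252; 8.30, adjusted p = 0.00117), rose. pspC, a prespore gene, fell (-1.46, adjusted p = 0.00841; -1.27, adjusted p = 0.0124), and psvA fell on S. salivarius (-1.74, adjusted p = 0.0445) but did not pass on S. mutans (-0.27, adjusted p = 0.723), with no difference between the streptococci shown (adjusted p = 0.33).

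Among lysosomal glycosidases and hydrolases (0.335 and 0.266; of 32, 4 higher and 5 lower, then 3 and 7), glb2, a beta-galactosidase gene (3.08, adjusted p = 0.00117; 3.76, adjusted p = 0.000479), and plbD, a phospholipase B-like gene (2.54, adjusted p = 0.00419; 3.29, adjusted p = 0.0012), rose while plbE (-1.05, adjusted p = 0.025; -2.37, adjusted p = 0.000639) fell. Among polyketide synthases (0.978 and 0.787; of 29, 2 higher and 4 lower, then 3 and 4), pks16 (-1.55, adjusted p = 0.03; -3.52, adjusted p = 0.000902) and stlB, which makes the precursor of the stalk inducer DIF-1 (-1.50, adjusted p = 0.00664; -1.05, adjusted p = 0.0247), fell and pks13 rose (2.07, adjusted p = 0.0108; 1.85, adjusted p = 0.0139). Of the ABC transporters (0.225 and 0.104; of 60, 3 higher and 8 lower, then 4 and 11), abcG4 rose (5.33, adjusted p = 0.00089; 4.93, adjusted p = 0.00115) and abcB6 fell (-2.08, adjusted p = 0.002; -1.56, adjusted p = 0.00607). Of 14 Cbp calcium-binding protein genes, 8 rose and 0 fell in each comparison, a family chosen because members of it were among the largest rises, so no test of it as a set is given. Of 32 cytochrome P450 genes 6 rose and 4 fell on S. salivarius and 12 rose and 5 fell on S. mutans.

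S. mutans replicate 1 lay nearer the S. salivarius libraries than S. mutans replicates 2 and 3. The tables argue against sequencing depth: after all libraries were thinned to the smallest total, the difference between its mean correlations stayed at 0.0455 (0.0454 to 0.0457 in 20 thinnings, 0.0460 at full depth). A wrong label could account for it, but this stays undecided. On 500 genes that separate the groups without it, its median position was 0.0294, within the range of the S. salivarius libraries (-0.0440 to 0.226). On that scale 0 is the S. salivarius mean and 1 that of S. mutans replicates 2 and 3. The genes were chosen for setting replicates 2 and 3 apart. Such a position would also arise if those 2 libraries differed in stage, so it does not speak for a wrong label in particular. In S. mutans replicate 1, nramp1, chosen after its values were seen, was at 36.6 CPM. Its group, that library included, averaged 37.1 ± 0.571, and S. salivarius 78.5 ± 4.8. Without that library the log2 difference between the streptococci also moved little for other named genes, such as mcm6 (1.846 to 1.898) and gpi (0.908 to 0.985). It widened for others, such as rps29 (1.414 to 2.446) and alyA (1.774 to 2.662). The genes mcm6 and gpi were named for a small p with that library included, which favours genes on which it lies with its group. These genes therefore exclude nothing. S. mutans replicates 2 and 3 may instead be further along in development, and this stays open, since prespore and spore markers were higher in them by a median of 0.61 on the log2 scale, at percentile 92.6 of 10000 random lists matched on expression, under the 95th percentile (0.69). Of the other lists set against random lists, early development genes lay at percentile 93.07 (0.12) and prestalk markers at 91.72 (0.41), the Tgr family at 99.53 (1.28, above its 95th percentile of 0.82), discoidins at 20.31 (-0.94) and cytosolic ribosomal proteins at 0 (-2.23). The design names no difference between replicates, so no biological explanation that it gives was tested.

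Far fewer genes were called between the streptococci than against E. coli. Spread among the S. mutans libraries may account for part of this: without S. mutans replicate 1, which had been seen to lie with the S. salivarius libraries, 1574 genes passed, against 0 with it. The same fit called 3061 and 3955 genes against E. coli, so fewer genes were still called between the streptococci. The food bacteria may also act on these cells in part alike, which was not tested apart from the overlap of both responses. For chance, 3 libraries against 3 allow 10 splits, too few for a share under 0.05: the real splits gave 2122, 2791 and 0 genes and the highest of the others gave 0 in each comparison, so that 1, 1 and 10 of the 10 splits gave as many genes as the real one.

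Of 27 early development genes, 18 were higher on S. salivarius and 21 on S. mutans, the other 9 and 6 not passing, and the list as a set did not pass with an estimated correlation (adjusted p = 0.28 and 0.243). The tables argue against fewer ribosomal protein reads leaving more room for all other genes, since the median of the list exceeded that of all genes by at least 2.22 on the log2 scale in both comparisons, where such room would raise all genes alike (a single check, since a scaling hardly moves this excess), and against E. coli replicate 1 as the source, since without it the medians were 2.23 and 2.52, against 2.28 and 2.51 with it. Without that library 17 of 18 and 18 of 21 calls held, the second under the 9 in 10 set beforehand, a bound that took no account of the loss of a library's degree of freedom. Cells on streptococci may have been short of food, a candidate explanation that cannot be told apart from a direct response to the bacteria because each food is 1 group: lysosomal proteases and ribosomal proteins, lists of growing cells, had medians of -0.80 or lower in both comparisons, but were chosen after those falls had been seen, so they decide nothing. Ribosome biogenesis, also a list of growing cells, lay the other way (medians of 2.41 and 2.73), as did nucleotide synthesis on S. salivarius (1.35), while on S. mutans that list did not pass (0.66, camera adjusted p = 0.147; 7 of 23 higher, 2 lower). That the amoebae respond to the kind of bacterium as such stays open, untested.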
